A study of Homo sapiens with 9 samples.

How the data were processed

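HuR-bound RNA from 9 HITS-CLIP libraries was measured: 3 of parental 293T cells and 3 of each of 2 Dicer-null clones. The submitters' processing notes name Bowtie2, TopHat, DESeq2 and the build hg19, without versions or roles, and the peak caller is not given in the sources used here. The values came in a single table of 16 columns with a row per peak, in which every peak belonged to the class of 3′ UTR exons.

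The authors deposited for each peak a parental mean and a Dicer-null mean, a normalized signal named a base mean per the file headers. That these are means over libraries of reads divided by a size factor, with 6 libraries of both clones in the Dicer-null mean, was found in the values themselves. The authors also deposited a log2 fold change of Dicer-null against parental, and a p-value and an adjusted p-value per peak. That deposited log2 value is not the log2 ratio of the means: it was smaller in size in 2311 of the 2744 peaks with both means above 0 and had the opposite sign in 574. The authors deposited an FPKM per gene, whose sample is not given in the sources used here, and the ratio of the parental mean to that FPKM. Marks for overlap with an Ago2 site and for an Ago2 site on the 3′ UTR are, per the file headers, deposited per peak, and how the Ago2 sites were defined is not given in the sources used here. Positions are hg19 as deposited, written 1-based.

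No column held a value per library, so the planned test per library could not be run as designed. After the data were examined, whole reads were recovered from the means. Each mean is a sum of whole reads times what 1 read is worth in each library, and a search found 3 such values in the parental means and 6 in the Dicer-null means. Unique whole reads were found for 2810 parental means and for 2808 Dicer-null means, within the rounding of the deposited 15 digits, with a largest residual of 4.5e-13. The remaining Dicer-null means lay above the upper limit set for the search and were not tried. On simulated means, 100% of values were solved with the true reads. A normalized read is a read divided by the recovered size factor, so that 1 read was worth 0.249 in Dicer-null library A and 6.98 in Dicer-null library F. The recovered reads were tested with limma 3.58.1 (voom, R 4.3.3) with the recovered size factors, and shares and sums per library with exact two-sided permutation tests over the 84 ways to pick 3 of the 9 libraries, with Benjamini-Hochberg adjustment. Pooled read ratios carry exact conditional 95% intervals. In the simulation of 200 changed peaks among 2808, with an assumed negative binomial size of 3, no unchanged peak was called and 3.57% of them had an unadjusted p under 0.05 in the run with 8-fold changes.

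A genome of the build hg19 was not used here. Peak sequences were placed by exact match in GENCODE transcripts of their own gene, with no conversion of coordinates, which placed 2721 of 2810 peaks in a 3′ UTR. Of the 1366 gene names, 1340 matched directly, 24 through current or older symbols, and 2 did not match. Motifs in a peak were compared with a window of equal width 200 nt from its edge, in no peak, by the exact two-sided McNemar test. When peak and flank were swapped at random, 10 of 200 runs had a p under 0.05. Pentamers were ranked by the z of the difference in shares of windows. Seed matches were 7-mers to positions of 13 miRNA families, counted within 50 nt of the peak centre and in windows 200 to 400 nt away, with 100 permuted sets as controls. Gene lists, 15 in all, were compared with other protein-coding genes by Fisher's exact test, and with 10000 random lists matched on 3′ UTR length. Comparisons across peaks or genes used 100000 permutations of the median difference, two-sided, adjusted over 15 tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0 were used.

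The gene lists, seed families, motifs, pentamers, position test and most of their alternatives were fixed before the data were examined. The comparisons by Ago2 mark, the shares of reads by library, class and list, the sums per gene, the match to other genes and the limma-voom fits were chosen afterwards. So were the boundary of 2000 reads and the UHMK1 map. Genes named in the text are the 15 with most peaks, those of the 10 strongest peaks, up to 6 members of each list with a peak and up to 3 without, and ELAVL1 and DICER1. Alternatives included peaks of higher strength, other flank and seed distances, shuffled and composition-paired backgrounds, other 3′ UTR annotations and length-matched lists. Those chosen after seeing the data left out each library in turn or the 3 libraries under 2000 reads, scaled by reads in peaks, or fitted a term for those 3 libraries. Whether a share of reads depended on a setting was judged first on unadjusted p and then, after the outcome was seen, on adjusted p over the 5 classes. Shares of transcript regions and strength by region were not computed because the table held 3′ UTR peaks alone.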

Results

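HuR, the protein product of ELAVL1, is an RNA-binding protein that recognises U-rich and AU-rich stretches in mRNAs and is known for stabilising many of them. Its contacts with RNA were mapped by HITS-CLIP, in which cells are crosslinked, the protein is immunoprecipitated from lysate and the attached RNA fragments are sequenced. The cells were 293T, a human embryonic kidney line, and 2 derived clones, NoDice 2-20 and NoDice 4-25, which lack Dicer, the enzyme that cuts miRNA precursors into mature miRNAs. Each of the 3 groups had 3 libraries, 9 in all. The series asks how HuR and the miRNA machinery meet on the same mRNAs. The measurements were 2810 HuR peaks on the 3′ UTRs of 1366 genes, each with an authors' mean of normalized reads for the parental libraries and for the Dicer-null libraries of both clones together, so the clones are not compared here.

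The whole reads behind each mean could be recovered by arithmetic for 2808 of the 2810 peaks, which gave the depth of each library, though not its replicate number or clone. The libraries are therefore called parental library A to C and Dicer-null library A to F, in order of depth. Parental libraries A, B and C held 15228, 8215 and 1452 reads in peaks. Dicer-null libraries A to F held 21419, 13647, 10923, 4931, 213 and 162 reads. These totals, and the shares of reads built on them, leave out the 2 peaks that were not recovered, in SRSF6 and PCBP1, which are also the strongest. The median peak held 16 reads over the 9 libraries, 5 of them parental and 11 Dicer-null, and the lowest total was 10. The 3 libraries under 2000 reads in peaks were parental C and Dicer-null E and F. Across peaks, which are not independent replicates, their read counts correlated with those of the other 6 libraries at a Spearman coefficient of 0.0868 to 0.151, against 0.246 to 0.428 among the 6. Among themselves these 3 libraries correlated at 0.199 to 0.205, above their values with any of the 6. Values are therefore also given for the 6 libraries with over 2000 reads. Nothing in the labels says whether libraries of a group came from separate cultures. A p-value is therefore set against the spread between libraries of unknown kind, and intervals on reads cover counting error only. Tests between the groups also count the 6 Dicer-null libraries as separate units, although they came from 2 clones. Other differences of these clones from the parental line cannot be told apart from loss of Dicer.

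**Figure D1:**
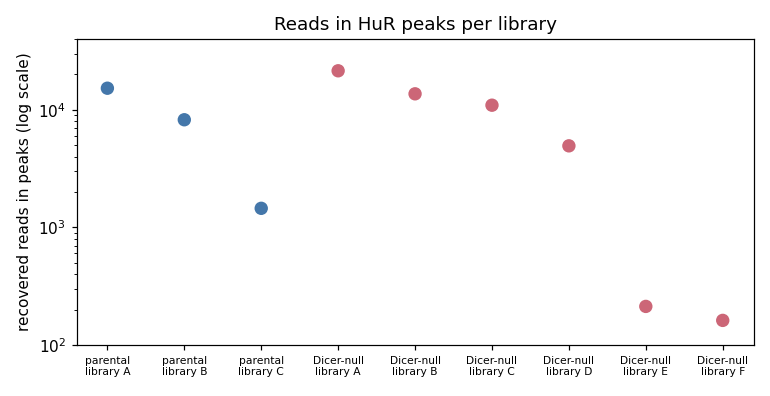
Reads in HuR peaks (y axis, log scale, whole reads recovered from the authors' means) for each of the 9 libraries, parental in blue and Dicer-null in red. Parental library C (1452 reads) and Dicer-null libraries E and F (213 and 162 reads) lie below the other 6, which hold 4931 to 21419 reads.

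HuR binding was spread over many genes, with a few 3′ UTRs that carried many peaks. CCND2, which encodes the G1 cyclin D2, carried 30 peaks between positions 4409147 and 4414476 of chromosome 12 (hg19, as all coordinates here). DDX17, an RNA helicase that works with the miRNA processing complex, and LARP1, which binds mRNAs of the translation apparatus, carried 27 each. NUCKS1 carried 23, the chaperone gene CANX and MIDN 20 each, TNPO2 17, HCFC1 and STARD7 16 each, and MAZ 15. SLC7A5, an amino acid transporter, and TXLNA and UHMK1, a kinase gene, carried 14 each, and the helicase gene DDX6 and the splicing factor gene SRSF1 carried 13. In contrast, 834 of the 1366 genes, 61.1%, carried a single peak. ELAVL1 itself carried 6 peaks on its 3′ UTR, between 8027092 and 8028368 of chromosome 19 on the minus strand. DICER1 carried no peak, and the loss of Dicer was not checked in these data. Peaks had a median width of 34 nt, with quartiles of 27 and 45 nt.

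The strongest peak by the mean of both group means lay in the 3′ UTR of SRSF6, a splicing factor gene, at 42090018 to 42090040 of chromosome 20 (ATTTCAGCAGGATCTGCTGGCAG). It had an authors' mean of 175.7 normalized reads in parental and 169.0 in Dicer-null libraries. Next came PCBP1, a poly(C)-binding protein gene, at 70316158 to 70316183 of chromosome 2 (AGTTTTGTTTTGGGTTTTTTGGCTCA), with 91.0 and 82.9. These 2 peaks are the ones whose Dicer-null reads were not recovered, because their means lay above the upper limit of the search. The peak of the tubulin gene TUBB at 30692275 to 30692305 of chromosome 6 (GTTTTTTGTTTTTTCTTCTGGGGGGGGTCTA) had 52.9 and 32.3. RAD23B, a DNA repair gene, had 42.2 and 36.2 at 110092642 to 110092671 of chromosome 9 (ATTTTTTTTTTGTTTTGGGGAAAAAATTGG). The other genes among the 10 strongest peaks were TMEM107, HNRNPA0, UBE2N, PABPN1, the transcription factor gene JUND and the actin-binding protein gene PFN1. The TMEM107 peak, at 8076812 to 8076886 of chromosome 17, matched the small nucleolar RNA SNORD118 over its whole length, so its reads cannot be assigned to either transcript. Of the peaks searched in genes whose names matched the annotation, 33, or 1.18%, had a full match in a gene of another name. Across genes, which are not independent replicates, the parental mean summed over a gene correlated with the authors' FPKM at a Spearman coefficient of 0.187 (permutation p = 0.0001, the smallest that 10000 permutations give).

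HuR peaks were rich in runs of U, read here as T. TTTTT stood in 39.4% of the 2426 peaks with a usable flank (95% exact interval 37.5 to 41.4) and in 15.95% of equally wide windows 200 nt away in the same 3′ UTR (14.5 to 17.5). TTTNTTT stood in 33.1% of peaks and 9.11% of flanks. The longer AU-rich motif, TTTATTT or TATTTAT, stood in 4.82% of peaks and 3.34% of flanks. The short AU-rich motif ATTTA went the other way, with 3.17% of peaks and 7.997% of flanks. All 4 differences passed the exact two-sided McNemar test after Benjamini-Hochberg adjustment, at 2.0e-72 for TTTTT, 3.1e-93 for TTTNTTT, 0.0101 for the longer AU-rich motif and 1.1e-13 for ATTTA. Dinucleotide-shuffled peaks keep the count of every pair of neighbouring bases, TT included, and so keep much of any run of T. This background therefore cannot tell base composition from a preference for runs of T. Against dinucleotide-shuffled peaks, TTTTT stood in 37.6% of peaks and 35.3% of shuffled sequences (exact two-sided McNemar test, adjusted p = 0.00437). TTTNTTT stood in 31.6% and 23.7% (exact two-sided McNemar test, adjusted p = 1.0e-24). The longer AU-rich motif stood in 4.73% and 2.10% (adjusted p = 3.0e-09), a wider gap than with flanks. The difference for ATTTA was then -0.747 percentage points and missed the threshold (adjusted p = 0.124).

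**Figure D2:**
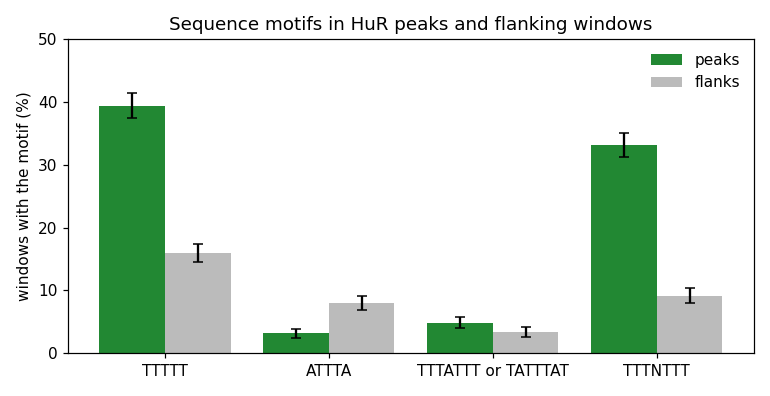
Share of windows with each motif (y axis, percent) in 2426 HuR peaks (green) and in equally wide flanking windows 200 nt away (grey), with exact 95% intervals as error bars. TTTTT stands in 39.4% of peaks and 15.95% of flanks, and ATTTA in 3.17% and 7.997%.

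Among all pentamers, TTTTG led, in 38.7% of peaks and 11.05% of flanks, followed by TTTTT. TTTGG stood in 24.6% and 5.94%, and GGAAG, without U, in 17.8% and 4.16%. All 20 leading pentamers lacked C, and 9 of them held 3 or more G. The pentamers most depleted in peaks were TATTA, in 0.907% of peaks and 5.56% of flanks, and TAATA, in 0.536% and 4.74%. Peaks held more G than flanks, at a mean of 26.1% ± 8.69 against 20.4% ± 9.60 (SD over 2426 windows each).

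Sites of Ago2, the Argonaute protein that carries miRNAs, overlapped 502 peaks, 17.9% of the total (95% exact interval 16.5 to 19.3), by the authors' marking. A further 1413 peaks lay in genes with an Ago2 site elsewhere on the 3′ UTR, and 895 in genes without a site. Genes with an Ago2 site, such as CCND2, DDX17 and LARP1, carried 2.43 HuR peaks on average, and the 578 genes without a site, such as SLC7A5, carried 1.55 (permutation p = 1e-05, the smallest that 100000 permutations give; adjusted p = 3.0e-05 over 15 tests). Genes with a site also had the higher median FPKM, 12.5 against 9.96 (adjusted permutation p = 0.00015), and the parental sum over FPKM was 0.116 against 0.114 (adjusted permutation p = 0.822). Across genes, the number of peaks correlated with FPKM at a Spearman coefficient of 0.251. Length of the 3′ UTR was not matched in this comparison. Protein-coding genes with a HuR peak had a median longest 3′ UTR of 2450 nt, and those without a peak 1209.5 nt. Peaks on Ago2 sites were stronger than other peaks of such genes, in tests across peaks, which are not independent replicates. Their median for the mean of both group means was 0.978, against 0.807 (adjusted permutation p = 3.0e-05). The parental mean over FPKM had medians of 0.0491 and 0.0421, a difference that missed the threshold (adjusted permutation p = 0.102). Peaks on Ago2 sites were also less U-rich than those other peaks. TTTTT stood in 20.7% of the former (17.3 to 24.5) and 40.2% of the latter (37.6 to 42.8; Fisher's exact test, adjusted p = 3.1e-15).

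Matches to the seeds of 13 abundant miRNA families were more frequent around peaks on Ago2 sites. How those sites were defined is not given, so whether seed matches were used to call them, which would fix this difference, is unknown. The compared peaks also differed in composition, with a median of 31.0% T on Ago2 sites and 36.7% T elsewhere. The permuted 7-mers and the A+T pairing below were run over all peaks, not for this contrast. Within 50 nt of the centre, 26.3% of 448 Ago2-overlapping peaks had a match (95% exact interval 22.3 to 30.7), against 7.48% of 1337 other peaks of genes with an Ago2 site (6.13 to 9.02; Fisher's exact test, p = 6.2e-23). Over all 2570 peaks with usable windows, 11.1% had a match and 9.26% of windows 200 to 400 nt away did (exact two-sided McNemar test, p = 0.0362), a difference in points that 1 of 100 permuted sets of 7-mers reached. The family with the clearest difference was miR-19, with 52 peak windows and 25 distant windows (adjusted p = 0.0364), and the let-7 family had 17 and 11 (adjusted p = 0.756). The difference over all peaks missed the threshold within 25 nt (exact McNemar p = 0.230) and within 100 nt of the centre (exact McNemar p = 0.656). With windows paired within 10 percentage points of A+T content it was -0.408 percentage points (exact McNemar p = 0.681). With 8mer matches, 4.90% of peak windows and 2.996% of distant windows had a match (exact McNemar p = 0.000672).

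Peaks lay somewhat towards the start of the 3′ UTR. The median relative position of the 2721 peaks placed in the longest annotated 3′ UTR was 0.438 (95% bootstrap interval 0.419 to 0.460), where 100 random placements gave medians of 0.477 to 0.527. In the shortest annotated 3′ UTR that held each peak, the median was 0.506, inside the range of random placements, 0.478 to 0.526.

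Genes for RNA-binding and splicing proteins, and known targets of HuR, held peaks far more often than other protein-coding genes, of which 6.83% held a peak over all. In the list of ARE-binding proteins and their paralogs, 17 of 30 genes held a peak. The list is broad and also holds PCBP1, a poly(C)-binding protein gene, with 5 peaks. Others were IGF2BP1 with 12 peaks, the decay factor gene KHSRP with 10, CELF1 with 7, and FMR1 and HNRNPK with 4 each. The neuronal HuR paralogs ELAVL2, ELAVL3 and ELAVL4 held none. Among SR splicing factors, 8 of 12 genes held a peak, including SRSF1, SRSF2 with 7 peaks, and TRA2A and SRSF6 with 5 each. Among 41 known HuR targets, 17 held a peak, including the nucleolar protein gene NCL with 6 peaks, and ACTB and JUN with 5 each, while ATF3, BCL2 and CCNB1 held none. The adjusted p-values were 1.1e-11, 9.0e-07 and 3.3e-09 by Fisher's exact test with Benjamini-Hochberg adjustment over 15 lists.

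The miRNA machinery was itself bound, with peaks in 7 of 21 genes (adjusted p = 0.000848). Beside DDX17 and DDX6, these included TNRC6B with 9 peaks, TNRC6A and DDX5 with 2 each and ADAR with 1, the TNRC6 proteins being partners of Argonaute in silencing. AGO1, AGO2 and AGO3 held none. Cell cycle regulators held peaks in 10 of 32 genes (adjusted p = 0.000103), including CDC25A, CDK6 and WEE1 with 4 each, and ubiquitin-conjugating enzymes in 9 of 26 (adjusted p = 0.000103), including UBE2N with 4. Genes of mRNA decay held peaks in 7 of 35, among them BTG1 and CNOT6 (adjusted p = 0.0182), a call that was lost against random lists with the same 3′ UTR lengths (adjusted p = 0.106). Ribosomal protein genes, including RPL15 with 2 peaks, held peaks in 9 of 75 (adjusted p = 0.189, but 0.0309 against random lists with the same 3′ UTR lengths), MAPK and PI3K signalling genes in 3 of 27, including NRAS (0.641), glycolysis genes in 2 of 18, GPI and PGK1 (0.585), and nuclear-encoded genes of oxidative phosphorylation in 3 of 35 (0.914). Markers of blood and immune cells (16 genes), of liver and pancreas (12) and of muscle and skin (12) held none, and of 14 neuronal markers NEFL alone held a peak. All bound genes had an FPKM of at least 1.02 and expression of the other genes was not used here, so these shares mix expression with binding.

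The comparison of Dicer-null with parental cells asks whether HuR binding differs where miRNAs are missing. No peak passed an adjusted p of 0.05 in the authors' deposited table, where the lowest adjusted p was 0.999. At an unadjusted p under 0.05 the authors' deposited table held 14 peaks, 7 higher and 7 lower in Dicer-null cells, where 140.5 would be expected from uniform p-values. The lowest p in the authors' deposited table, 0.00463, belonged to HNRNPA0, a splicing regulator gene, at 137088500 to 137088525 of chromosome 5 (log2 fold change -1.10). Its reads were 60, 39 and 80 in parental libraries A, B and C, so that the shallow library C held the most. In the 6 libraries with over 2000 reads, limma-voom gave this HNRNPA0 peak a log2 fold change of -0.50 (standard error 0.31). UBE2N, an enzyme that builds K63-linked ubiquitin chains, followed with a log2 fold change of -0.82 in the authors' deposited table, and the cadherin gene CDH2, chosen after its values were seen, had -1.67. On the higher side, the authors' deposited table gave the chaperone gene CALR, also chosen after its values were seen, a log2 fold change of 1.06, with 40 parental and 143 Dicer-null reads, and the TMEM107 peak that matched SNORD118 0.65.

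The median log2 fold change over all peaks in the authors' deposited table was 0.22, and 72.3% of peaks lay above 0, although the summed Dicer-null means were 0.973 times the summed parental means. The median log2 ratio of the means in the authors' deposited table was 0.080, and in 546 peaks the deposited log2 fold change was above 0 while that ratio was below. The excess shrank with depth. Peaks with 10 to 12 reads had a median of 0.24 (95% bootstrap interval 0.22 to 0.27) and the 95 peaks with over 100 reads a median of 0.032 (-0.042 to 0.12).

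**Figure D3:**
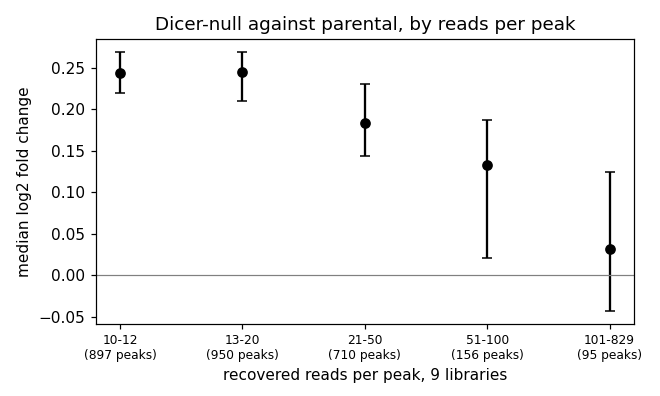
Median log2 fold change of Dicer-null against parental in the authors' deposited table (y axis) for peaks grouped by recovered reads over the 9 libraries (x axis), with bootstrap 95% intervals as error bars. The median is 0.24 for peaks with 10 to 12 reads and 0.032 for peaks with over 100.

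A test on the recovered reads gave the same count of calls. limma-voom over the 9 libraries called 0 of 2808 peaks at an adjusted p under 0.05, with a lowest adjusted p of 0.501, and 264 at an unadjusted p under 0.05, 220 of them higher in Dicer-null libraries. limma-voom adds 0.5 to every count. In Dicer-null libraries E and F, with 0 reads in 93.8% and 95.1% of peaks, that entered as 3.21 and 3.49 normalized reads, above the median Dicer-null mean of 0.838 over peaks. The excess of 220 over the rest therefore cannot be read as gained binding. The count of 264 fell to 99 without parental library A and to 127 without parental library C, with 0 called each time. Scaled by reads in peaks, limma-voom called 0 and gave 38 at an unadjusted p under 0.05, 11 of them higher and 27 lower. Without the 3 libraries under 2000 reads it called 0 as well, with 172 peaks at an unadjusted p under 0.05, 86 in each direction. On simulated reads with 200 changed peaks it called 0 at 2-fold and at 4-fold and 56 at 8-fold, so changes of up to 4-fold were not detectable under the spread that was assumed.

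The kinase gene UHMK1 had the most one-sided reads among the genes with many peaks, although no gene passed adjustment. Reads were summed over each 3′ UTR in the 6 libraries with over 2000 reads. UHMK1 had 35.9 ± 3.76 normalized reads in Dicer-null libraries (SD, n = 4) and 11.9 ± 3.11 in parental libraries (SD, n = 2), a ratio of pooled reads of 3.15 (95% exact interval 2.35 to 4.29). All 14 of its peaks had a log2 fold change above 0 in the authors' deposited table, from 0.45 to 1.46. The ratios were 2.43 for SLC7A5 (1.79 to 3.37), 2.06 for MIDN (1.72 to 2.50), 1.95 for TNRC6B (1.42 to 2.72) and 1.69 for CCND2 (1.40 to 2.06). Ratios below 1 were found for UBE2N, at 0.682 (0.569 to 0.818), TRA2A, at 0.706 (0.574 to 0.870), and TUBB, at 0.722 (0.632 to 0.826). Some of these leaned on parental library A. Without it the ratio was 1.58 for SLC7A5 (1.06 to 2.42) and 0.897 for TUBB (0.729 to 1.11), whose interval then held 1. ELAVL1 had a ratio of 0.873 (0.640 to 1.20). Of 75 named genes, 10 had an interval above 1 and 6 an interval below 1, with counting error alone taken into account. Over 9 libraries, the lowest exact permutation p among 75 named genes was 0.0357, for HNRNPA0, and the lowest adjusted p was 1. Without the 3 libraries under 2000 reads, the exact permutation p of HNRNPA0 was 0.333. With 2 parental and 4 Dicer-null libraries no exact p can fall under 0.0667, the value that UHMK1, MIDN, TNRC6B and UBE2N were among those to reach. The exact permutation p was 0.133 for CCND2 and TUBB and 0.267 for SLC7A5.

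**Figure D4:**
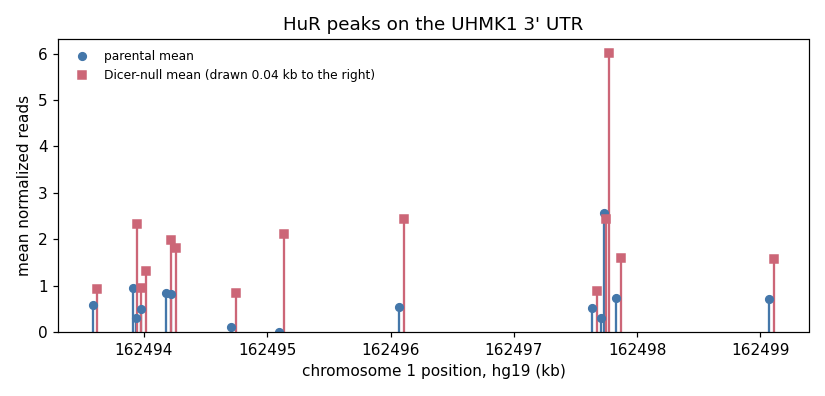
Authors' mean normalized reads (y axis) of the 14 HuR peaks on the UHMK1 3′ UTR by position on chromosome 1 (x axis, kb, hg19), for parental (blue circles) and Dicer-null libraries (red squares). The Dicer-null mean is the higher of the pair at every peak, with log2 fold changes of 0.45 to 1.46 in the authors' deposited table.

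No gene list differed in its share of the reads after adjustment. UBE2N and CCND2 held most of the difference in the lists with the lowest p over 9 libraries. Ubiquitin-conjugating enzymes took 1.42% ± 0.257 of reads in parental libraries (SD, n = 3) and 0.865% ± 0.134 in Dicer-null libraries (SD, n = 6; exact two-sided permutation p = 0.0119, the smallest possible, adjusted p = 0.131 over 11 lists). Without UBE2N, their shares were 0.371% ± 0.0288 and 0.394% ± 0.157 (exact permutation p = 0.762). Cell cycle regulators took 1.01% ± 0.374 and 1.43% ± 0.238 (exact permutation p = 0.0357, adjusted p = 0.196), and without CCND2 0.518% ± 0.188 and 0.540% ± 0.214 (exact permutation p = 0.929). In the 6 libraries with over 2000 reads, the exact permutation p was 0.0667, the smallest possible, for 4 lists: ubiquitin-conjugating enzymes, the miRNA machinery (2.40% parental and 2.79% Dicer-null), MAPK and PI3K signalling, and oxidative phosphorylation. It was 0.533 for cell cycle regulators. Without CCND2, cell cycle regulators there took the larger share in parental libraries, 0.605% against 0.421% (exact permutation p = 0.0667). Without DDX17, the miRNA machinery took 0.925% of parental and 1.05% of Dicer-null reads in those 6 libraries (exact permutation p = 0.133). The miRNA machinery took 2.20% ± 0.372 and 2.61% ± 0.618 (exact permutation p = 0.345), and known HuR targets 2.37% ± 0.290 and 2.16% ± 0.432 (exact permutation p = 0.452).

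Genes with an Ago2 site, among them CCND2 and UHMK1, had slightly higher log2 fold changes than genes without, in a test across genes, which are not independent replicates. The test across libraries did not pass adjustment. In the authors' deposited table the median log2 fold change per gene was 0.22 for the 788 genes with a site and 0.16 for the 578 without. The difference of 0.065 (95% bootstrap interval 0.015 to 0.11) had a permutation p of 0.0029 and an adjusted p of 0.00483. Reads in peaks of genes with an Ago2 site made up 70.3% ± 1.56 of parental libraries (SD, n = 3) and 74.5% ± 2.46 of Dicer-null libraries (SD, n = 6; exact two-sided permutation p = 0.0476, adjusted p = 0.238 over 5 classes). The unadjusted p was 0.05 or more in 7 of the 9 exact tests that left out a library, and at most 0.0714. In the 6 libraries with over 2000 reads the shares were 71.2% ± 0.518 (SD, n = 2) and 73.0% ± 0.365 (SD, n = 4; exact permutation p = 0.0667, the smallest possible). Whether a peak itself overlapped an Ago2 site made no detectable difference, with medians of 0.22 and 0.24 in the authors' deposited table (difference -0.022, 95% bootstrap interval -0.068 to 0.039; permutation p = 0.514). The difference between genes missed the threshold when each gene was represented by its strongest peak (0.043, permutation p = 0.0672), and the data do not separate binding from mRNA abundance.

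**Figure D5:**
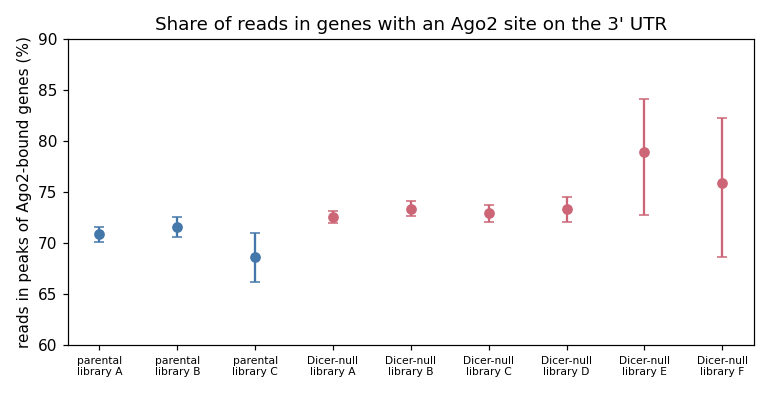
Share of each library's reads in peaks of genes with an Ago2 site on the 3′ UTR (y axis, percent, from 60 to 90), with exact 95% intervals, for parental (blue) and Dicer-null libraries (red). The parental libraries lie between 68.6% and 71.6% and the Dicer-null libraries between 72.6% and 78.9%.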

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

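The tests of counting error, of one error in the size factors of each group and of Ago2-bound mRNAs alone, and the comparison by Ago2 site itself, were chosen after the result was seen. Dicer-null library E stood apart from the other Dicer-null libraries in the share of its reads in peaks overlapping an Ago2 site, at 40.8%, where the other 5 lay between 23.7% and 29.6%. Chance sets a library apart in this way in about 1 of 20 groups where all libraries have the same spread, and 5 classes of reads were examined. With 213 reads, library E has a larger counting error than the deeper libraries, so that rate does not hold here. Counting error about the level of the others is argued against by the exact interval of its 213 reads, which starts at 34.2%, although the interval of library F, 22.7% to 37.3%, overlaps it. The other 2 libraries under 2000 reads, parental C at 31.4% (29.02% to 33.9%) and Dicer-null F at 29.6%, also lay above the 6 deeper ones, at 23.5% to 27.1%, so a high share was not particular to library E. Without its peaks in PABPN1, HOXB9 and ATP6V1A, the last 2 named after their values were seen, the share was 40.2% (33.3% to 47.4%). Of these, the PABPN1 peak alone, with 7 reads, overlaps an Ago2 site, so only its removal could lower the share. CALR, which overlaps a site, tied with ATP6V1A at 3 reads and was kept. The PABPN1 peak therefore does not carry the share, and no biological explanation was tested because the clone of library E is not known.

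The median log2 fold change of 0.22 in the authors' deposited table was above 0 while the group sums were nearly equal and the median log2 ratio of the means was 0.080. An error of one amount in the size factors of each group would shift the ratios of means of weak and strong peaks alike. The deposited log2 values were mostly smaller in size than those ratios, so they need not shift alike. Medians of peaks with 10 to 12 and with over 100 reads differed by 0.21, with intervals that did not overlap. For that reason this difference cannot decide on such an error. Scaling by reads in peaks moved the median log2 value of limma-voom from 0.39 to 0.16. Loss of Dicer acting on Ago2-bound mRNAs alone would leave genes without an Ago2 site at 0, if no general shift moved all genes. Their median was 0.16 (95% bootstrap interval 0.13 to 0.20). A general shift was not excluded above and would move these genes too, so this median cannot decide on that explanation. A minimum of reads per peak stays open. Peaks were grouped by their reads in parental library A and Dicer-null library B. The Dicer-null over parental ratio was then taken in Dicer-null libraries A, C and D over parental library B alone. It was 1.13 (1.06 to 1.20) for peaks with 10 to 19 reads and 0.988 (0.913 to 1.07) for those with 40 or more. These intervals resample peaks, not libraries, and overlap, so they decide nothing. Every peak also held at least 10 reads over the 9 libraries, so the choice was not independent of the libraries compared.

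Genes with an Ago2 site had the higher log2 fold change, and loss of miRNA-guided silencing may be behind it. Median reads per peak were 16 in genes with a site and 15 in genes without. Matching them could therefore change little, and the number of peaks per gene was not matched. Unequal reads per peak as the whole cause is argued against by the difference of 0.065 that remained after this matching (95% bootstrap interval 0.012 to 0.11). Whether the 3 libraries under 2000 reads carry it cannot be told apart: in the other 6 the difference was 0.075, with an interval from 0 to 0.206 that holds both 0, which by the bound set beforehand would have counted for those libraries, and the value of all 9. A role of miRNA sites is open too, since genes with a seed match on the 3′ UTR had a median 0.024 above genes without, as did 52 of 100 sets of permuted 7-mers. The bound set beforehand against that role was 50 sets; both readings were left open after the values were seen, because 52 is within counting error of 50 and 0.206 reaches past the 9-library value.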

How the results depend on the processing

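The leave-one-out fits, the fits without the 3 libraries under 2000 reads, the other scaling, the term for those 3 libraries and the Ago2 alternatives were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate number, and replicates were not guessed from the values. A term for the 3 libraries under 2000 reads gave 253 peaks at an unadjusted p under 0.05 in limma-voom, against 264, and 0 calls. Of 998 alternative values, 854 kept their direction and side of the threshold or moved little, 9 fell short of the threshold, 1 passed it and 5 moved. The sign changed in 129, of which 2 belonged to results past the threshold and 127 to results not past it. Most of these, 115, were normalized reads of single genes, in 47 of the 75 named genes, and 7 were read shares of gene lists. The difference in the read share of peaks overlapping an Ago2 site was 1.04 points in 9 libraries, -0.363 in 6, -0.861 without parental library A and -1.46 without Dicer-null library E. That of peaks with GGGG was -2.68 points, and 1.47 without parental library C. The log2 difference of peaks overlapping an Ago2 site was 0.011 against all other peaks. The 1405 peaks of higher strength are fewer by construction. The ATTTA difference was -0.747 percentage points against shuffled peaks. Seed matches differed by 0.828 points within 25 nt, 0.541 within 100 nt and -0.408 with paired A+T content. In the shortest 3′ UTR, peaks lay 0.0052 beyond the random median. For mRNA decay genes, 3.05 with a peak were expected in length-matched lists and 4 held a peak of higher strength, neither of which passed; for ribosomal protein genes 3.46 were expected, which made their 9 pass. The log2 difference between genes with and without an Ago2 site was 0.048 in peaks of higher strength, 0.059 in genes with 1 peak, 0.043 for each gene's strongest peak and 0.075 in 6 libraries, none past the threshold. The cause was not tested for any of these. limma-voom called 0 peaks each time; at an unadjusted p under 0.05 it gave 172 without the 3 libraries, and 38 when scaled by reads in peaks, which moved the median log2 value from 0.39 to 0.16. Leaving out a library gave 99 (parental A) to 307 (Dicer-null D), and 127 without parental C. The unadjusted exact p of the read share in genes with an Ago2 site ran from 0.0179 to 0.0714 over the leave-one-outs and was 0.05 or more in 7. Merging touching peaks left 2810. Transcript regions, strength by region, a replicate block, count tools on the design's terms and no count filter were not run. Depth limits the comparison, at a median of 16 reads per peak.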

Other observations

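The genes and classes in this part were picked after the data were examined, while the count of splits was set before its outcome was seen. Several genes outside the lists carried many peaks. APLP2 carried 10 peaks and 907 reads, SLC16A1, a lactate transporter gene, 11 peaks and 427 reads, SCD, which encodes a fatty acid desaturase, 11 peaks, ALKBH5, which removes methyl marks from RNA, 11 peaks, and SFPQ, a nuclear RNA-binding protein gene, 10. Of 103 genes with 5 or more peaks, 18 had all their log2 fold changes above 0 in the authors' deposited table and 0 had all below, where 72.3% of all peaks were above 0. Beside UHMK1, the 18 included GIGYF1, a repressor of translation, with 8 peaks from 0.42 to 1.46, and MKNK2, a kinase of the cap-binding factor, with 5 peaks from 0.50 to 0.93.

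The bases of a peak were unevenly placed along it. T made up 41.6% of bases between 20% and 40% of the width from the 5′ end and 31.0% between 60% and 80%, while G rose from 25.2% to 31.0%. A run of 4 or more T with a run of 4 or more G after it stood in 5 of the 10 strongest peaks, those of TUBB, HNRNPA0, UBE2N, RAD23B and PFN1, and in 252 of all 2810 peaks, 8.97%. The opposite order stood in 118, 4.199%. Peaks with GGGG took 37.1% of the reads of parental library C (95% exact interval 34.6 to 39.6) and 24.6% of those of parental library A (23.9 to 25.3). In Dicer-null libraries E and F, also under 2000 reads, the shares were 32.9% (26.6 to 39.6) and 28.4% (21.6 to 36.0).

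Like that of TMEM107, the RPS3A peak at 152024980 to 152025029 of chromosome 4 matched a small RNA over its whole length, SNORD73A.

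Of the 84 splits of the 9 libraries into 3 and 6, 5 gave at least the 264 peaks at an unadjusted p under 0.05 of the real split, the real one included, and the highest of the others gave 422, so chance was not excluded. The 4 others each put Dicer-null libraries E and F together in the group of 3. With parental library C they gave 299 and called 28 peaks after adjustment, where the real split called 0. The 0.5 that limma-voom adds entered as 3.21 and 3.49 normalized reads in Dicer-null E and F, with 0 reads in 93.8% and 95.1% of peaks. A split with both in the group of 3 can gain low p-values from that alone. Other such splits gave fewer peaks at an unadjusted p under 0.05, down to 148 with parental library A. Whether depth or a shared preparation adds to this was not tested. The 6 libraries with over 2000 reads gave 172, and a fit with a term for the 3 gave 253.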
